A study of Rattus norvegicus with 13 samples.

How the data were processed

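Pancreatic islets of male Sprague-Dawley rats were treated for 18 h with an adenovirus and then cultured for 60 h more, at 8 mM glucose and 10% serum, with about 200 islets per condition and 500 ng of RNA per labelling, per the labels. The virus carried beta-galactosidase as the control (bGAL, 5 arrays), hamster Nkx6.1 (5 arrays) or mouse Pdx1 (3 arrays). The labels call the arrays of a group independent islet isolations, so each array was taken as 1 biological replicate. The authors amplified the RNA, labelled the islet RNA with Cy5 and hybridized it together with a Cy3-labelled commercial rat reference RNA to spotted rat oligonucleotide arrays.

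The deposited values are log2 ratios of islet RNA over reference RNA, with each array centred near a median of 0. That the log is to base 2 was inferred from the values, since base 10 or base e would need ratios beyond the range of the scanner. The direction of the ratio follows from the dyes and was checked on the probes of the islet hormones, which lay far above 0, and of albumin, which lay far below 0. The background correction, the normalization within arrays and the rule that left values empty are not given in the sources used here. The values used here are log ratios alone, so signal over background could not be examined, and the number of arrays limits the precision of every value.

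The table held 26984 probes, of which 22 were control spots and were left out of the comparisons. Of the other 26962 probes, 15807 carried 1 gene symbol, 0 carried several and 11155 carried none here. Symbols were compared with current rat gene names: 12049 were current, 3707 were updated from an older symbol and 51 were not matched. No probe position on the genome was given in the sources used here, so none is reported. Probes with at least 2 values in every group were tested (17965 probes, 11234 of them with a symbol), and 8997 probes were left out by this filter. The value of a gene in the list tests was the mean over its probes with a value on every array. A gene without such a probe took its most complete probe alone. This gave 9799 genes.

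Group differences came from limma (version 3.58.1 in R 4.3.3, with statmod 1.5.0), as 1 model with 3 groups over all 13 arrays, moderated variances without a trend, two-sided tests and Benjamini-Hochberg adjustment over the probes tested, with a threshold of 0.05 on the adjusted p. The comparisons were Nkx6.1 with bGAL, Pdx1 with bGAL and Nkx6.1 with Pdx1. Differences are log2, the first group minus the second. Vgf, the gene behind the peptide in the series title, also had a two-sided exact permutation test of the difference of means over all splits of the arrays. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists within a comparison, with lists of at least 5 measured genes. Beside it stand camera with a correlation estimated for each list and the directional test of fry, which asks whether a list's own genes move and does not compare them with other genes.

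The 28 lists, with 814 genes between them, covered granins and prohormone processing, neuropeptides, exocytosis, G1/S and DNA replication, mitosis, cell-cycle inhibitors and p53 targets, immediate early genes, the unfolded protein response, glycolysis, mitochondrial energy metabolism, cholesterol and fatty acid synthesis, hypoxia, interferon, NF-kB, apoptosis, islet disallowed genes, islet transcription factors, channels, cAMP signalling, ribosomal proteins, and markers of beta cells, alpha and other hormone cells, acinar, ductal, fibroblast, endothelial, macrophage and glial cells. The comparisons, tests, threshold, lists and naming rule, and all alternatives but 4, were chosen before the data were examined.

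Genes are named by this rule. Nkx6-1, Pdx1 and Vgf are named first. For each comparison with bGAL, the 12 largest rises and the 12 largest falls are taken among probes that passed the threshold, carried 1 symbol and had group values that did not overlap, 1 probe per gene. Comparing Nkx6.1 with Pdx1, the 6 largest in each direction are taken. For each list described, up to 4 members with the smallest p are taken. Of the genes past the threshold in both comparisons with bGAL, the 6 with the largest shared change are taken. A gene named outside this rule is said to be chosen after its values were seen.

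Arrays differed widely in the share of probes left empty, and 5 arrays with over 30% empty (bGAL 1, 2, 3 and 5 and Nkx6.1 1) were treated as an array set apart from the other 8. This set was defined from the data and is not a group of the study. The alternatives added after seeing the data were the array set as a block, that block without Nkx6.1 replicate 2, the 8 arrays with few empty values alone, and every array scaled to one spread. The alternatives chosen beforehand were centring each array on its median, quantile normalization, only probes with a value on all 13 arrays (9241 probes), only probes with 1 symbol, a variance trend with robust moderation, array weights, the replicate number as a fixed or a random block, only the arrays of the groups compared, a difference of at least 1, the list tests named above, separate controls for the comparisons with bGAL, and each array left out in turn.

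The procedure was tested on simulated data of the same size, with 50 changed probes at each of 4 sizes. Each value was drawn independently around the bGAL mean, without an effect of the array set. The recovery and false calls therefore hold for such data and do not give the error in the real arrays. At a true log2 difference of 1, 2, 3 and 4 it recovered 20%, 66%, 76% and 100% of the changed probes for Nkx6.1 against bGAL, with 7 false calls among 138. For Pdx1 against bGAL it recovered 14%, 58%, 92% and 94%, with 8 false calls among 137, and for Nkx6.1 against Pdx1 12%, 60%, 84% and 90%, with 14 false calls among 137. The arrays were also compared for duplicates, and 0 pairs shared identical values. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.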

Results

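Expression was measured in rat islets after transfer of the homeobox factors Nkx6.1 (5 arrays) or Pdx1 (3 arrays), both regulators of beta-cell development, or of beta-galactosidase as a control (bGAL, 5 arrays). The series title concerns a peptide derived from Vgf, a secreted granin-like protein of neuroendocrine cells. Each array compared islet RNA with the same reference RNA pool, so a log2 ratio of 0 means equal signal in islets and reference. The arrays held values for 10475 (Nkx6.1 1) to 26900 (Pdx1 1) of the 26962 probes that are not controls, and their median log2 ratios lay between -0.06 and 0.00.

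The share of probes without a value separated the arrays in a way that the groups only partly followed. It was 35.4% to 61.2% on bGAL 1, 2, 3 and 5 and on Nkx6.1 1, and 0.23% to 15.5% on the other 8 arrays, which held 1 bGAL, 4 Nkx6.1 and all 3 Pdx1 arrays. Over the 9241 probes with a value on all arrays, the SD was 1.78 to 1.90 on the first set and 1.43 to 1.501 on the others, leaving out Nkx6.1 replicate 2 with 2.13. That replicate also stood apart in its correlation across probes with the other arrays, 0.557 to 0.725, against 0.821 to 0.971 among the other 12 arrays. Probes within an array are not independent replicates. Values within 0.01 of a log2 ratio of 0 numbered 374 to 1796 per array, 1.80 to 3.82 times those between 0.01 and 0.02 from it, and up to 89 probes of an array held the same value there. Such a value is also what 2 channels without signal would give. The signals were not available, so the size of a difference from such values is uncertain.

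**Figure D1:**
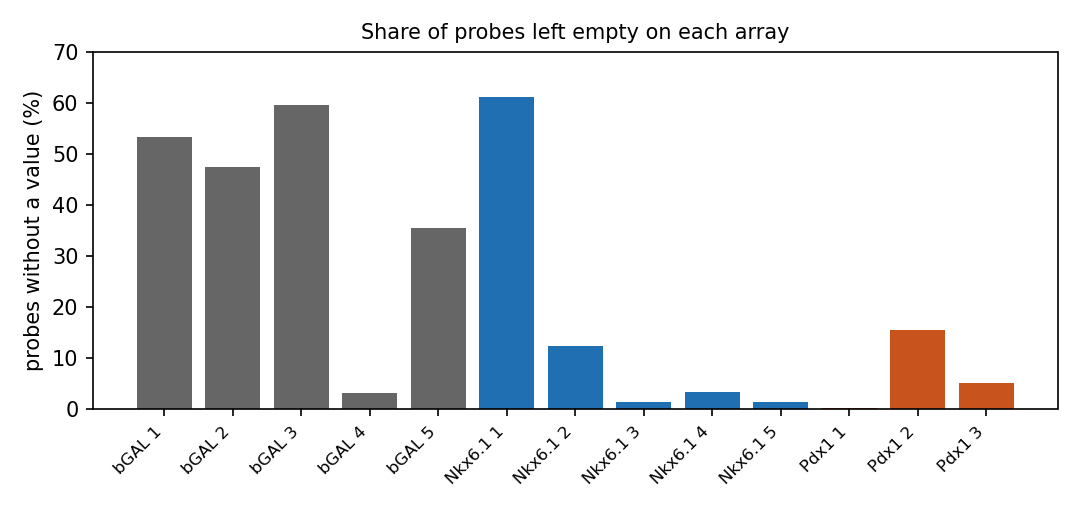
Percent of the probes without a value on each of the 13 arrays, as bars starting at 0 and grouped by virus. The 5 arrays over 30% are bGAL 1, 2, 3 and 5 and Nkx6.1 1, and no Pdx1 array is among them.

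The probe for Nkx6-1, the gene of the transferred factor, had a log2 ratio of 3.73 ± 0.314 under bGAL (SD, n = 5), 3.19 ± 0.582 under Nkx6.1 (n = 5) and 3.08 ± 0.510 under Pdx1 (n = 3). Its differences did not pass the limma test: -0.54 for Nkx6.1 against bGAL (adjusted p = 0.417), -0.65 for Pdx1 against bGAL (adjusted p = 0.503) and 0.11 between the factors (adjusted p = 0.940), with the other sign for all 3 under quantile normalization. The transferred cDNA is from hamster and the position of the rat probe is unknown, so this probe does not show whether the factor was made. The array carried 0 probes named Pdx1.

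Vgf stood at a log2 ratio of 1.72 ± 0.465 under bGAL (SD, n = 5), 3.74 ± 1.12 under Nkx6.1 (n = 5) and 1.34 ± 0.0465 under Pdx1 (n = 3). All 5 Nkx6.1 arrays lay above all bGAL arrays, with a difference of 2.02 (SE 0.448, 4.06-fold). The exact permutation test gave p = 0.00794, the smallest that 252 splits allow, while the limma test over all probes did not pass (adjusted p = 0.0659). Against Pdx1 the difference was 2.40 (5.28-fold; exact p = 0.0179, the smallest that 56 splits allow; limma adjusted p = 0.111). Over all probes tested, group values did not overlap for 7.73% between Nkx6.1 and bGAL and for 12.1% between Nkx6.1 and Pdx1. Chance gives 0.794% and 3.57% for probes with a value on all arrays, and more for others. These exact p values alone therefore do not set Vgf apart. Under Pdx1, Vgf differed from bGAL by -0.38 (SE 0.517, exact permutation p = 0.196, limma adjusted p = 0.850), and by 0.25 under quantile normalization. Nkx6.1 replicate 2 held the highest Vgf value, 5.73 against 2.95 to 3.41 on the other 4. Without it the difference from bGAL was 1.53 and passed (adjusted p = 0.00723), as it did without bGAL 4 (1.96, adjusted p = 0.0452). The Vgf difference from bGAL was 1.63 within the arrays with many empty values, which hold 1 Nkx6.1 array, and 2.35 within those with few, which hold 1 bGAL array. With the array set as a block it was 1.99 (adjusted p = 0.447), and over all alternatives that adjusted p ran from 0.00239 to 0.990.

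**Figure D2:**
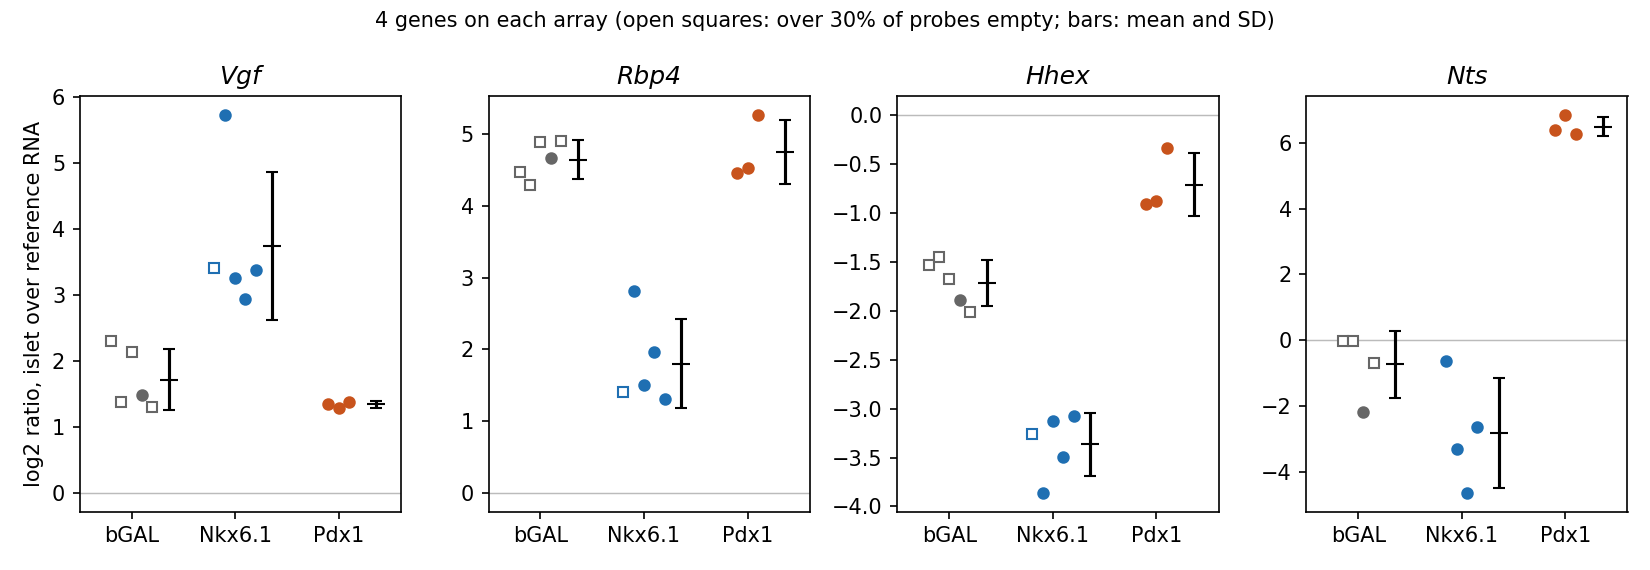
Log2 ratio of islet over reference RNA of Vgf, Rbp4, Hhex and Nts on each array, by virus, with the mean as a bar and the SD as its error. Open squares mark arrays with many empty values. The 5 Nkx6.1 arrays lie above all bGAL arrays for Vgf and below them for Rbp4 and Hhex, and the 3 Pdx1 arrays lie above all others for Nts.

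Comparing Nkx6.1 with bGAL asks what the factor changes in islet gene expression. Genes of cell division rose together. Cdk1, the kinase that drives entry into mitosis, was higher by 2.65 (SE 0.212, 6.28-fold, adjusted p = 1.98e-04) in 5 of 5 Nkx6.1 arrays, and Stmn1, Plk1 and Hmmr by 1.57, 1.91 and 2.01 (adjusted p = 0.00148, 0.00182 and 0.00238). Of 37 measured mitosis genes, 15 rose and 0 fell, 25 rose when adjusted over the list alone, and the median difference was 1.13 (camera adjusted p = 5.16e-26). Array by array, the mitosis median lay at 1.05 to 1.31 above the bGAL mean under Nkx6.1, against -0.06 to 0.18 on the bGAL arrays themselves. Genes of G1/S and DNA replication had a median of 0.70 over 34 genes (camera adjusted p = 2.11e-09). Of these E2f8, a cell-cycle transcription repressor, rose by 2.44 (SE 0.283, adjusted p = 0.00203) and Ccna2, cyclin A2, by 2.04 (adjusted p = 0.0441). In all 14 rose when adjusted over the list alone. Rpa2 (0.82, adjusted p = 0.0633) and Mcm6 (1.11, adjusted p = 0.0678) did not pass singly. With an estimated correlation the mitosis list (adjusted p = 7.06e-04) and the G1/S list (adjusted p = 0.00126) also passed. The 13 cell-cycle inhibitors and p53 targets did not pass camera under Nkx6.1 (median 0.10, adjusted p = 0.0931), with 0 past limma, 5 at an unadjusted p under 0.05 and 4 higher when adjusted over the list alone. They passed fry (adjusted p = 0.00182 over 7 genes) and passed camera without Nkx6.1 2 (0.23, adjusted p = 0.0327).

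Rbp4, a retinol-binding protein abundant in islets and listed with hormone cells other than beta cells, fell by 2.84 on the log2 scale (SE 0.297, 7.18-fold, adjusted p = 0.00148), from 4.64 ± 0.268 under bGAL (SD, n = 5) to 1.80 ± 0.620 (n = 5). Hhex, a transcription factor of delta cells, fell by 1.65 (SE 0.215, adjusted p = 0.00406). They were the 2 of 15 genes of that list that passed. Among its other members Slc7a2 and Fev differed by -2.38 and 0.65 without passing. Slc7a2 differed by -0.58 with the array set as a block, and its second probe by -0.39 without the block. The list as a whole did not pass (median -0.27, which turned to 0.49 under quantile normalization, camera adjusted p = 0.163). It did pass without Nkx6.1 replicate 2 (median -0.51, adjusted p = 1.11e-04) and with the array set as a block (-0.12, adjusted p = 0.0118). The call of Rbp4 was lost under quantile normalization (-2.15, adjusted p = 0.115) and that of Hhex with the array set as a block (-1.55, adjusted p = 0.0691). Across all alternatives the adjusted p ran from 1.15e-04 to 0.549 for Rbp4 and from 7.56e-04 to 0.7496 for Hhex.

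The NF-kB, interferon and immediate early lists also passed upward under Nkx6.1. Among 22 NF-kB genes the median was 0.53 (camera adjusted p = 2.04e-04; adjusted p = 0.140 with an estimated correlation). Without Nkx6.1 replicate 2 that median was 0.26, still past the threshold (camera adjusted p = 1.11e-04). The adhesion molecule Icam1 rose by 2.09 (SE 0.353, adjusted p = 0.0202), and 6 rose when adjusted over the list alone. The chemokine genes Cx3cl1 (2.68, adjusted p = 0.0512), Cxcl2 (2.00, adjusted p = 0.0599) and Cxcl1 (0.96, adjusted p = 0.158) did not pass over all probes, and stood at 1.73, 1.54 and 1.02 with the array set as a block. The 24 interferon genes passed (camera adjusted p = 0.00816; adjusted p = 0.246 with an estimated correlation) with a median of 0.06 and a mean of 0.37. Among them Oasl, an antiviral enzyme relative, rose by 2.53 (adjusted p = 0.0202, bGAL n = 2), and the immunoproteasome subunits Psmb9 and Psmb8 by 1.67 and 1.03 (adjusted p = 0.0213 and 0.0387). Irf7 differed by 1.80 without passing (adjusted p = 0.0727). Adjusted over the list alone, 7 interferon genes rose and 1 fell. That list's call was lost without bGAL 4 (median -0.01, adjusted p = 0.0662) and without Nkx6.1 replicate 3 (0.07, adjusted p = 0.0537). Its median was 0.13, 0.14, 0.11 and 0.03 without bGAL 1, 2, 3 and 5 and 0.26 without Nkx6.1 2. The 33 immediate early genes had a median of 0.27 (camera adjusted p = 0.00126; adjusted p = 0.140 with an estimated correlation). Of them the phosphatase Dusp1 rose by 1.20 (SE 0.163, adjusted p = 0.00491), and 4 rose when adjusted over the list alone. Pde4b, Dusp6 and Nr4a1 differed by 0.96, 1.05 and 0.85 without passing. Dusp1 did not pass under quantile normalization (0.91, adjusted p = 0.204) or with arrays scaled to one spread (1.06, adjusted p = 0.173). Neither did the immediate early list under quantile normalization (0.17, adjusted p = 0.0533), nor within the arrays with few empty values (0.19 over the 36 genes measured there, adjusted p = 0.178).

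Among all probes, the largest rises by the naming rule, after those given, were in Cenpt (2.98), the securin gene Pttg1 (2.95), Rnase3 (2.63, with 2.61 on its second probe), the lipid droplet gene Cidea (2.62, SE 0.344, adjusted p = 0.00407), Fanca (2.56), the mitotic kinase gene Mastl (2.38), Ptgis (2.37), Hsd11b2 (2.35) and Cdc20 (2.24). Other probes of Cenpt (-0.42) and Fanca (-0.65 and -0.42) did not share the rise. These 9 rises stood with the block at 2.61, 2.84, 2.04, 2.604, 2.10, 2.34, 2.30, 1.78 and 2.11 in the same order, and none passed. The largest falls were in Prm1 (-5.13), Unc13c (-4.66), Unc119b (-4.65), Or7g16 (-4.63), Taar1 (-4.41), Fmn2 (-3.76, bGAL n = 2), Lrrn3 (-3.01), Tram1l1 (-2.99), the peptide hormone genes Gast (-2.94, bGAL n = 2) and Calcb (-2.79), and Siglec5 (-2.75). Second probes of Unc13c, Fmn2 and Siglec5 differed by 0.21, 0.04 and 0.26. The bGAL values of Prm1, Or7g16, Taar1 and Unc119b scattered by an SD of 2.44, 2.26, 2.14 and 2.00. None of these 11 falls passed with the array set as a block, and for 10 of them, all but Lrrn3, no value on Nkx6.1 1 was left, so that the blocked difference compared the other Nkx6.1 arrays with bGAL 4 alone. They stood at -3.56 for Prm1, -3.13 for Unc13c, -3.31 for Unc119b, -2.51 for Or7g16, -0.74 for Taar1, -3.39 for Fmn2, -3.56 for Lrrn3, -1.97 for Tram1l1, -2.71 for Gast, -1.85 for Calcb and -1.37 for Siglec5.

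In the limma test 115 of 17965 probes passed, 74 higher and 41 lower under Nkx6.1. Of these 90 carried a symbol and 108 differed by at least 1. Over all probes 2595 had an unadjusted p under 0.05 where chance gives 898. With the array set as a block 1071 did, so most of that excess was lost. The group values of 112 of the 115 did not overlap, as for 7.73% of all probes tested. Chance gives 0.794% for probes with a value on all arrays, and more for probes with empty values. The size of the excess is therefore uncertain. With the array set as a block 13 probes passed, all 13 among the 115, with Cdk1 (2.75), Rbp4 (-2.997), Stmn1 (1.62), Plk1 (1.89) and E2f8 (2.04) among them. The blocked medians were 1.17 for mitosis, 0.65 for G1/S, 0.52 for NF-kB, 0.43 for interferon and 0.38 for immediate early genes, all 5 lists still past the threshold. Within the arrays with many empty values the same medians were 1.42, 0.73, 0.95, 0.61 and 0.44, and within those with few 1.17, 0.56, 0.46, 0.26 and 0.28. Within the few-empty arrays, which hold 1 bGAL array, fewer probes passed limma than with the block. Fewer also had an unadjusted p under 0.05 than chance gives. The lone bGAL array there was assumed to vary like the other groups. Of 33 named calls in this comparison, 5 passed with the block: Cdk1, Rbp4, Stmn1, Plk1 and E2f8. With each array left out in turn 14 passed in every fit that held them: those 5 with Hhex, Hmmr, Dusp1, Cidea, Mastl, Ptgis, Fanca, Calcb and Gast. Gast had bGAL values on only 2 arrays. Without either of these the probe filter dropped it, so its call was not tested there. The others, Ccna2, Icam1, Oasl, Psmb8 and Psmb9 among them, lost their call without at least 1 array. The count moved to 62, 39, 46 and 595 without bGAL 1, 2, 3 and 4, to 233, 47, 50 and 39 without Nkx6.1 2, 3, 4 and 5, and to 57, 59 and 47 without Pdx1 1, 2 and 3, which enter through the shared variance and the probe filter. Without bGAL 4 most calls were lower, 394 against 201 higher, among 14638 probes tested.

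**Figure D3:**
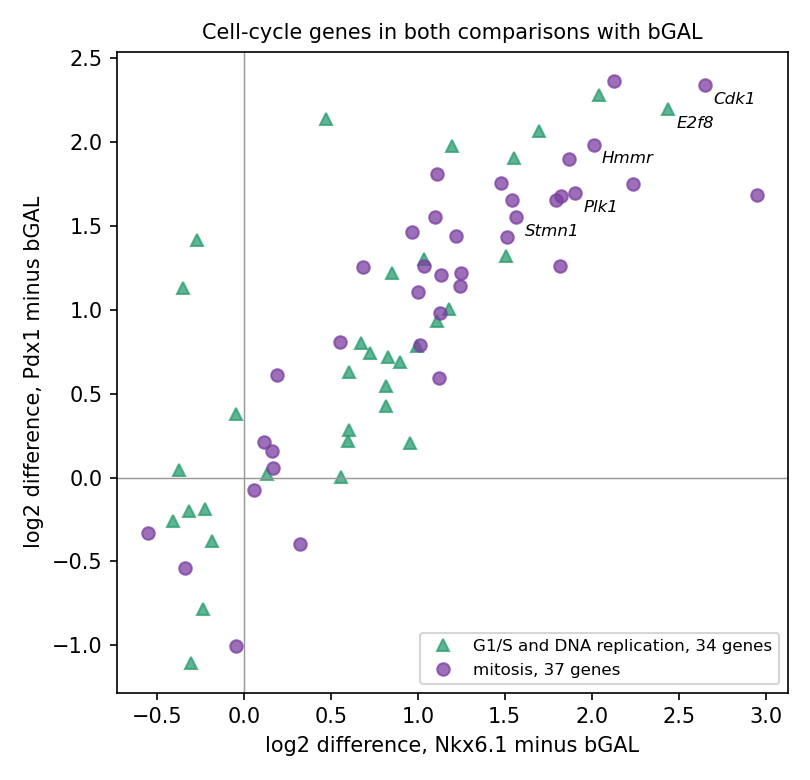
Log2 difference from bGAL of each measured mitosis gene (37) and G1/S gene (34), under Nkx6.1 on the x axis and under Pdx1 on the y axis, 1 point per gene. Cdk1, Plk1, Hmmr, Stmn1 and E2f8 lie high on both axes.

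Comparing Pdx1 with bGAL asks the same of the second factor. The neuropeptide gene Nts, neurotensin, went from a log2 ratio of -0.72 ± 1.02 under bGAL (SD, n = 4) to 6.49 ± 0.3001 under Pdx1 (n = 3), a rise of 7.21 (SE 0.804, 148-fold, adjusted p = 0.00288). The amino acid transporter gene Slc6a15 rose by 4.34 (SE 0.314, adjusted p = 6.20e-04) and Calb2, the calcium-binding protein calretinin, by 3.91 (SE 0.379, adjusted p = 0.00319), both with bGAL n = 2. Both bGAL values of Slc6a15 lay within 0.01 of 0, as did 1 of the 2 for Calb2, for Gpr149 and for Oasl, 1 of the 4 for Nts, and 2 of the 3 Pdx1 values of Gast, so the sizes of these differences are uncertain. Other large rises were in Tubb6 (3.54), Gpr149 (3.12, bGAL n = 2), Kcnq5 (3.08), Il13ra2 (2.99), Gpr37 (2.94), Adcy2 (2.91), the mitotic kinase gene Pbk (2.88), Olr1428 (2.73) and Id4 (2.62). Under the block these 9 did not pass and stood at 2.37, 3.05, 3.63, 3.06, 2.32, 2.24, 3.34, 2.37 and 3.26 in the same order. Among 21 neuropeptide genes, Nts and Penk (1.81, adjusted p = 0.0385) rose, and Calcb (-2.95, adjusted p = 0.00677) and Gast (-2.999, adjusted p = 0.00789, bGAL n = 2) fell. The list as a whole did not move one way (median -0.29, and 0.54 under quantile normalization; camera adjusted p = 0.973).

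Genes of cell division rose under Pdx1 as well. Cdk1 was higher by 2.34 (SE 0.244, 5.06-fold, adjusted p = 6.20e-04), Stmn1 by 1.55, Hmmr by 1.99 and Mad2l1 by 1.44 (adjusted p = 0.00288, 0.00622 and 0.00771). Of 37 mitosis genes 12 rose and 0 fell, 25 rose when adjusted over the list alone, and the median was 1.26 (camera adjusted p = 3.95e-28), at 1.29 to 1.41 above the bGAL mean on the 3 arrays. The 34 genes of G1/S and DNA replication had a median of 0.70 (camera adjusted p = 8.33e-11), with E2f8 higher by 2.20 (adjusted p = 0.00789). When adjusted over the list alone, 12 rose and 1 fell. Ccna2 (2.28), Mcm5 (1.90) and Cdc6 (2.07) did not pass over all probes, and stood at 2.56, 1.20 and 1.38 with the array set as a block. Of the 13 cell-cycle inhibitors and p53 targets 0 passed over all probes and 1 when adjusted over the list alone, with 3 at an unadjusted p under 0.05 in limma. The list passed with a median of 0.42 (camera adjusted p = 0.00541). Its members with the smallest p were Ccng1 (0.86), Gadd45a (0.87), Plk2 (1.20) and Gadd45b (1.01). In the fit with the block these stood at 0.80, 0.81, 0.37 and -0.10. These 3 lists also passed with an estimated correlation (adjusted p = 5.02e-04, 6.94e-04 and 0.0422). The 33 immediate early genes passed with camera alone (median 0.17, adjusted p = 0.0140; adjusted p = 0.245 with an estimated correlation). Of its genes 0 passed the limma test over all probes, 1 passed when adjusted over the list alone and 4 had an unadjusted p under 0.05. Its leading members were Dusp5 (1.41), Crem (-0.81), Areg (1.44) and Dusp6 (0.87). Within the arrays with few empty values Dusp5 and Crem stood at 1.22 and -0.40, Areg at 0.03 and Dusp6 at -0.04. That list's call was lost with the array set as a block (0.24, adjusted p = 0.0513), under quantile normalization (0.18, adjusted p = 0.2495), with arrays scaled to one spread (0.06, adjusted p = 0.392), with array weights (0.14, adjusted p = 0.0832) and within the few-empty arrays (adjusted p = 0.132). It was also lost without bGAL 5 (0.13, adjusted p = 0.0885), without Pdx1 2 (0.08, adjusted p = 0.0571) and in fry (adjusted p = 0.111). Without Pdx1 1 its median was 0.28 and passed.

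The largest falls under Pdx1, after Gast and Calcb, were in Aldh1a3 (-3.18, and -1.83 on its second probe), a retinoic acid synthesis enzyme gene, Bmp4 (-2.86), Map3k6 (-2.67), Trim50 (-2.36), the complement gene Cfb (-1.98), Plcb3 (-1.96), Elf1 (-1.86, and -0.44 on its second probe), Eloa (-1.83), Lbp (-1.82) and Cubn (-1.59, and 0.29 on its second probe). Of 4 bGAL values each, 2 of Aldh1a3 and 1 of Map3k6 lay within 0.01 of 0. None of these falls passed with the array set as a block. For all of them but Trim50 no value on Nkx6.1 1 was left, so that the blocked difference compared Pdx1 with bGAL 4 alone. They stood then at -2.77 for Gast, -2.01 for Calcb, -1.77 for Aldh1a3, -1.57 for Bmp4, -1.76 for Map3k6, -2.30 for Trim50, -1.09 for Cfb, -1.95 for Plcb3, -1.58 for Elf1, -1.34 for Eloa, -1.65 for Lbp and -1.27 for Cubn.

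For Pdx1 against bGAL 98 probes passed limma, 79 higher and 19 lower. Of these 71 carried a symbol and 98 differed by at least 1. Over all probes 2133 had an unadjusted p under 0.05, where chance gives 898. With the array set as a block 771 did, fewer than chance gives. The group values of all 98 did not overlap, as for 19.5% of all probes tested. For probes with a value on all arrays chance gives 3.57%, and for probes with empty values more. With the array set as a block 21 probes passed, all higher, with Nts (8.67), Slc6a15 (4.34), Calb2 (3.68), Cdk1 (2.48) and Stmn1 (1.62) among them. Nts, Slc6a15 and Calb2 had no value on Nkx6.1 1, so their blocked difference set 3 Pdx1 arrays against the single array bGAL 4, assumed to vary like the others. The blocked medians were 1.22 for mitosis, 0.54 for G1/S and 0.40 for cell-cycle inhibitors and p53 targets, the 3 lists still past the threshold. Within the arrays with few empty values, which hold all Pdx1 arrays and 1 bGAL array, 3 probes passed, and the same medians were 1.07, 0.54 and 0.40, though the third list lost its call in a test of those arrays alone (adjusted p = 0.204). No Pdx1 array had many empty values. Of 32 named calls, those 5 passed with the block, for 3 of them against 1 bGAL array. The same 5 passed with each array left out in turn, in every fit that held them. Slc6a15 and Calb2 had bGAL values on only 2 arrays. Without either of these the probe filter dropped them, so their calls were not tested there. The others, E2f8, Hmmr, Mad2l1, Penk, Calcb and Gast among them, lost their call without at least 1 array. The count moved to 52, 48, 59, 432 and 56 without bGAL 1, 2, 3, 4 and 5, to 321, 50 and 51 without Nkx6.1 2, 4 and 5, and to 24, 16 and 27 without Pdx1 1, 2 and 3. Without bGAL 4 the calls were 137 higher and 295 lower.

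The comparisons with bGAL shared 33 probes past the threshold in the same direction, 29 higher and 4 lower, and 0 in opposite directions. The named genes among them with the largest shared change were Cdk1, E2f8, Mastl and Ptgis, which rose under both factors, and Calcb and Gast, which fell under both. Independent lists of these sizes would share 0.325 higher and 0.0434 lower probes. Because the comparisons use the same bGAL arrays, 100 simulations of unchanged groups against the same controls were run. They shared 0 calls, but only 2 of them made any call for Pdx1 and 0 for Nkx6.1, so this count could not show sharing. Taking instead as many probes as were called, by smallest p, a count chosen after the data were seen, the simulations shared a median of 3.5 and at most 73. In 6 of the 100 they shared at least 33, so shared controls alone were able to give as many. Across all probes the log2 differences correlated at 0.695, against a simulated median of 0.610, so the correlation itself was near what shared controls give. The covariance was 0.367 against a highest simulated value of 0.298, and 0.1015 to 0.307 with separate controls. The simulations used deviations within groups, so they did not carry the difference in array set between bGAL and both factors. The excess is therefore no evidence of a shared effect of the factors. With separate controls for the factors, over 20 ways of dividing them, the correlation was 0.147 to 0.454, 0 to 8 probes were shared and the mitosis medians stayed between 1.00 and 1.46. With the array set as a block 6 probes were shared. The number moved to 21, 21 and 289 without bGAL 2, 3 and 4, to 103, 20 and 18 without Nkx6.1 2, 4 and 5, and to 8, 7 and 11 without Pdx1 1, 2 and 3.

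Comparing Nkx6.1 directly with Pdx1 tests the difference between the factors and uses the bGAL arrays only for the variance and the probe filter. Nts differed most, by -9.29, lower under Nkx6.1 (SE 0.804, 624-fold, adjusted p = 4.62e-04; Nkx6.1 n = 4, Pdx1 n = 3). Without Nkx6.1 replicate 2 it differed by -10.01 and without Nkx6.1 4 by -8.67, both past the threshold. It was followed by Slc6a15 (-4.73, adjusted p = 8.39e-05), Lrrn3 (-4.69, adjusted p = 0.00418), Calb2 (-3.47), Gpr149 (-3.47) and Enpp2, the gene of the secreted enzyme autotaxin (-3.42, adjusted p = 2.70e-05). Rbp4 (-2.95, SE 0.342, adjusted p = 0.00149) and Hhex (-2.65, SE 0.248, adjusted p = 2.66e-04) were lower under Nkx6.1 than under Pdx1 too. Higher under Nkx6.1 were Oasl (2.85, adjusted p = 0.00719), Ly6i (2.15, adjusted p = 0.0162) and Dusp1 (1.22, adjusted p = 0.0151). The 11 genes named here also passed with the array set as a block. That block left the differences of Nts, Slc6a15, Calb2, Gpr149 and Oasl as they were, because these had no value on Nkx6.1 1, and so tested nothing for them. With each array left out in turn 7 of the 11 passed in every fit that held them. The exceptions were Oasl (adjusted p up to 0.0675, without Pdx1 2), Ly6i (up to 0.145, without Pdx1 2), Dusp1 (up to 0.141, without Pdx1 3) and Lrrn3 (0.0524, without Pdx1 2). Slc6a15, Calb2, Gpr149 and Oasl had bGAL values on only 2 arrays. Without either of these the probe filter dropped them, so they were not tested there. Dusp1 did not pass under quantile normalization (1.53, limma adjusted p = 0.0796). With the replicate number as a fixed block, Slc6a15, Gpr149, Oasl, Calb2 and Dusp1 did not pass limma (adjusted p = 0.0534, 0.166, 0.167, 0.202 and 0.222). Rbp4 and Ly6i did not pass within the few-empty arrays. Enpp2, Nts and Hhex passed under every alternative that held them.

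NF-kB genes were higher under Nkx6.1 than under Pdx1, with a median of 0.85 over 22 genes (camera adjusted p = 5.93e-05; adjusted p = 0.322 with an estimated correlation). Of them 0 passed limma over all probes, 2 passed when adjusted over the list alone and 7 had an unadjusted p under 0.05. Its leading members included Icam1 (1.99) and Ccl20 (2.73). Interferon genes had a median of 0.41 over 24 genes (camera adjusted p = 0.00457; adjusted p = 0.454 with an estimated correlation), with Oasl past the threshold and 6 when adjusted over the list alone. That call was lost without bGAL 4 (adjusted p = 0.0514), bGAL 5 (adjusted p = 0.112) or Nkx6.1 3 (adjusted p = 0.0628). With an estimated correlation 0 lists passed this comparison, with 2 at an unadjusted p under 0.05, and fry passed 1. The blocked medians of these lists were 0.84 and 0.44, and those within the arrays with few empty values 0.86 and 0.39. The mitosis genes did not differ detectably between the factors (median 0.02, mean 0.05, test downward, camera adjusted p = 0.993), except with arrays scaled to one spread, where they were higher under Nkx6.1 (median 0.40, adjusted p = 0.00261).

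Between the factors 39 probes passed limma, 4 higher and 35 lower under Nkx6.1. Of these 29 carried a symbol. Over all probes 1231 had an unadjusted p under 0.05. All 39 had group values that did not overlap, as for 12.1% of all probes tested. For probes with a value on all arrays chance gives 3.57%, and for probes with empty values more. The array set as a block gave 44, and the arrays with few empty values, 4 Nkx6.1 and 3 Pdx1 beside 1 bGAL, gave 35. The count moved to 81, 24 and 19 without Nkx6.1 2, 3 and 4 and to 16, 14 and 17 without Pdx1 1, 2 and 3.

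**Figure D4:**
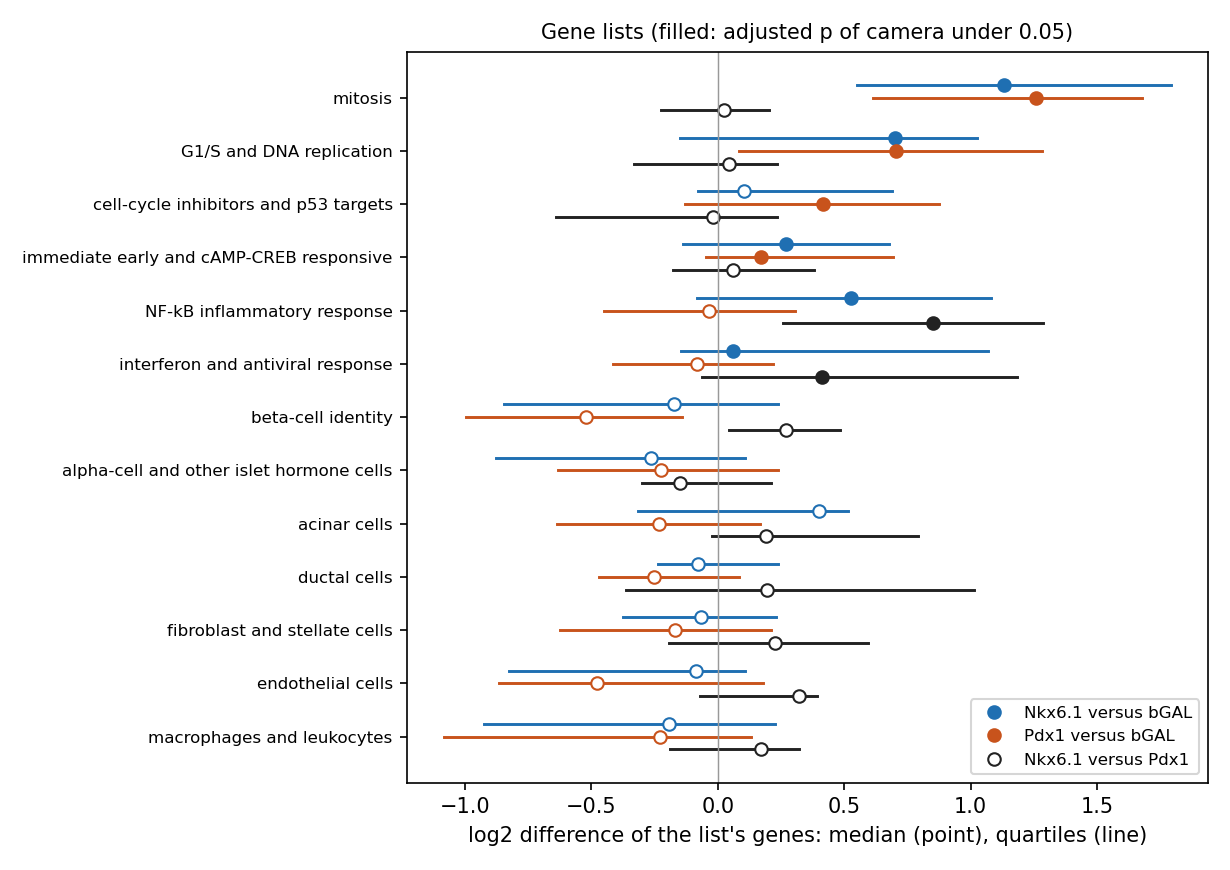
Median log2 difference of 13 gene lists, with quartiles as lines, in the 3 comparisons; filled symbols mark a camera adjusted p under 0.05. Mitosis and G1/S genes lie to the right of 0 in both comparisons with bGAL, and NF-kB and interferon genes are filled in both comparisons that involve Nkx6.1.

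The list of beta-cell identity, 21 genes of insulin production and glucose sensing, had 0 members past the limma threshold in any comparison, with 5, 2 and 1 at an unadjusted p under 0.05 for Nkx6.1 against bGAL, Pdx1 against bGAL and Nkx6.1 against Pdx1. Its medians were -0.17, -0.52 and 0.27 (camera adjusted p = 0.889, 0.217 and 0.456), and all changed sign under quantile normalization, to 0.89, 1.09 and -0.07 (adjusted p = 0.00249, 6.94e-04 and 0.609). Slc2a2, the islet glucose transporter gene, differed by 0.78 under Nkx6.1 (adjusted p = 0.162), and Abcc8, a subunit of the beta-cell potassium channel, by -0.90 under Pdx1 (adjusted p = 0.374), by 0.57 with quantile normalization, by -0.20 with the array set as a block and by -0.09 on its second probe. Granin and prohormone processing, with 19 genes, had 0 past limma as well, with 3, 3 and 1 at an unadjusted p under 0.05. Its medians were 0.24 (mean -0.27), -0.08 and 0.27, and under quantile normalization 1.19, 1.24 and -0.16 (adjusted p = 0.00249, 0.00138 and 0.779). Within the arrays with many empty values the medians for Nkx6.1 against bGAL were 0.24 for beta-cell identity and -0.09 for granins. Within those with few they were 0.13 and 0.13 for Nkx6.1 and 0.03 and -0.03 for Pdx1. The sign of the beta-cell medians against bGAL therefore depended on the scaling and on the array set.

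Markers of other cell types did not pass camera in any comparison with all arrays as deposited and no block. The medians for Nkx6.1 and then Pdx1 against bGAL were 0.40 and -0.23 for 17 acinar genes, -0.08 and -0.25 for 19 ductal genes, -0.07 and -0.17 for 25 fibroblast genes, -0.09 and -0.48 for 13 endothelial genes, -0.19 and -0.23 for 16 macrophage and leukocyte genes and -0.05 and -0.23 for 10 glial genes. Quantile normalization turned the ductal and glial medians positive under both factors, the endothelial one under Nkx6.1 and the acinar one under Pdx1. Under Pdx1 the fibroblast and macrophage lists passed downward with it (-0.33 and -0.46, adjusted p = 0.0172 for both). The fibroblast list also passed downward under Pdx1 with the array set as a block (-0.39, adjusted p = 0.0339). Within the arrays with many empty values the endothelial and glial medians under Nkx6.1 were 0.34 and 0.50, and within those with few 0.42 and 0.15 under Nkx6.1 and 0.02 and 0.30 under Pdx1. Fry passed the macrophage list under Nkx6.1 and Pdx1 (adjusted p = 0.0379 and 0.0454, 13 genes) and the endothelial list under Nkx6.1 (adjusted p = 0.0283, 3 genes).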

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

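The tests of the many-empty arrays, of cell-type markers for the mitosis genes, of a weaker hybridization and of a swap by correlation, mitosis genes and Nts were chosen only after the result was seen; the other tests here were written before. For values far from the rest of their group, 195 groups of 4 or 5 arrays were looked at, and 21 held one; chance gives about 1 in 20.

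Genes of mitosis rose under both factors. The array set with many empty values, which holds 4 of the 5 bGAL arrays, is argued against as the cause: with that set as a block the mitosis median kept at least 0.855 of its unblocked size in both comparisons and with each array left out in turn. The shared bGAL arrays are argued against too, since simulated unchanged groups reached a mitosis median of at most 0.264 while separate controls gave at least 1.00. More fibroblast, endothelial, duct or leukocyte cells would raise their markers. Under Pdx1 this is argued against: over the unblocked and blocked fits and the few-empty arrays the highest upper quartile of these lists was 0.329, against at least 0.536 for the mitosis medians divided by 2. Under Nkx6.1 it cannot be told apart. There the duct list reached an upper quartile of 0.861 on the single Nkx6.1 array with many empty values (median -0.04), against 0.7098 for the mitosis median divided by 2. With the block the endothelial median was 0.42 (upper quartile 0.53) and the upper quartile of the duct list 0.55, close to the 0.586 of the mitosis median divided by 2. Acinar and glial cells were not weighed here. A response of the islets to the factors stays open as an untested hypothesis.

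Replicate 2 of Nkx6.1 correlated least with the other arrays and held 13 of the far values given here. A weaker hybridization that compresses log ratios is argued against. The SD of this array over probes measured on all arrays was 2.13, against 1.44 to 1.78 for the other Nkx6.1 arrays. Its slope on their mean was 1.00. A hybridization poor in another way was not tested, since the signals were not available. A swap with a bGAL or Pdx1 array would not by itself explain its distance from all arrays. The other 12 arrays correlated with each other at 0.821 at least, but replicate 2 at most at 0.698 with any bGAL or Pdx1 array. With another Nkx6.1 array it reached 0.725 at most. Low correlations with every group are what set it apart, so they do not tell which group it came from. Its mitosis median stood 1.05 above the bGAL mean, against -0.06 to 0.18 on the bGAL arrays, and its Nts at -0.62 against 6.26 to 6.83 under Pdx1. The test written before did not decide, since 62.9% of 232 probes called without it lay nearer to the other Nkx6.1 arrays than to bGAL, under the 75% set for it. A sample from outside the series was not tested. RNA of acinar, duct, fibroblast, endothelial or leukocyte cells went against its own test, also written before, which asked for a median of over 1. Acinar genes, the highest of these 5 lists, stood above the other Nkx6.1 arrays by a median of 0.907 (quartiles 0.08 to 2.05). The list of islet hormone cells other than beta cells stood above by more, 1.52 (quartiles 0.40 to 2.48). These quartiles overlap and the acinar ones reach past 1, so such RNA is not excluded. No biological explanation was tested, because the labels set this replicate apart in nothing.

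Delta-cell genes Rbp4 and Hhex fell under Nkx6.1. With the array set with many empty values as a block, the differences were 1.05 (Rbp4) and 0.935 (Hhex) times the unblocked ones. Calls whose group values do not overlap largely keep their difference, with a median ratio of 0.938 over the 76 named calls. This ratio therefore cannot decide on the array set. Within the many-empty arrays, with 1 Nkx6.1 array, Rbp4 differed by -3.23 and Hhex by -1.59. Within the few-empty arrays, with 1 bGAL array, they differed by -2.76 and -1.50. Rbp4 still passed under the block, but the call of Hhex ended. The Hhex difference went from -1.65 (SE 0.215) to -1.55 (SE 0.274, limma adjusted p = 0.0691), nearly the same size with a larger error. A smaller share of delta cells would lower the delta-cell genes alike. Of 9 measured of 13 listed, 1 (11.1%) lay at or above 0, Prg4 at 0.97. The median was -1.02, or -0.37 without Nkx6.1 replicate 2. These 9 include Rbp4 and Hhex, whose fall prompted the test, so the median leans on them. Ptprz1 and Bche differed by -1.04 and -1.02, and Sec11c, Arg1 and Frzb by -0.34, -0.28 and -0.21. The lowest unadjusted limma p among these was 0.0704, for Ptprz1. Sst, somatostatin, differed by -1.09 and by -1.80 without that replicate, without passing. A loss of delta cells and a direct effect of Nkx6.1 on these genes cannot be told apart, since single genes scatter too widely around the median.

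On Nkx6.1 replicate 2 the log2 ratio lay far above the other Nkx6.1 arrays for Vgf (5.73, others 2.95 to 3.41), Cck (4.46, others 1.68 to 2.40), Gipr (7.51, others 4.57 to 5.35), Igf2 (7.25, others 4.22 to 4.85), Hsd11b2 (1.27, others -0.82 to -0.68), Icam1 (1.26, others -0.84 to -0.25), Mcm6 (-0.58, others -1.94 to -1.77), Nr4a1 (-2.49, others -3.57 to -3.27), Penk (-1.59, others -3.18 to -2.98), Psmb9 (2.00, others 0.82 to 1.13) and Pttg1 (2.04, others -0.99 to -0.81). It lay far below them for Pbk (-4.12, others -1.77 to -1.24) and Slc7a2 (-0.081, others 1.58 to 1.79, n = 4). Without this array Pttg1, Hsd11b2 and Icam1 were higher than under bGAL by 2.36, 1.94 and 1.72, and all 3 still passed.

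Elsewhere a single array lay far from its group for Dusp5 on Nkx6.1 3 (-2.08, others -1.24 to -0.98), Oasl on Nkx6.1 5 (2.22, others 3.05 to 3.14, n = 4), Ccl20 on bGAL 4 (-4.18, others -0.73 to -0.02), Map3k6 on bGAL 4 (-1.27, others -0.16 to 0.00, n = 4) and Saa3 on bGAL 1 (3.33, others 2.12 to 2.37). Of the measures per array, the empty share of Nkx6.1 1 (61.2%, others 1.48% to 12.4%), the SD of bGAL 4 over probes measured on all arrays (1.501, others 1.84 to 1.90) and the median of bGAL 1 (-0.065, others -0.019 to -0.005) lay far from the group.

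Of the 22 control spots, which entered no comparison, 20 had at least 2 bGAL values. On 2 of them every Nkx6.1 array with a value lay above every bGAL array. These were Alien_04, with a mean of 1.11 over 4 Nkx6.1 arrays against bGAL values of -0.12 to 0.39, and Rn_Control_08, with 0.32 against -0.16 to -0.08. Both had only 2 bGAL values. Values so few can separate by chance on some of 20 spots, which was not tested.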

How the results depend on the processing

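The array set as a block, that block without Nkx6.1 replicate 2, the arrays with few empty values alone and the scaling to one spread were chosen after the data were seen; all other alternatives were planned. Counts of probes were not stable over the alternatives. With the array set as a block all 76 calls of named genes kept their direction and 21 passed. The median ratio to the unblocked difference was 0.938. Nearly all called probes had group values that did not overlap, which largely fixes their direction under the block. The kept direction is therefore no evidence of stability. For 31 of the 76, 8 of them among those that passed, bGAL or Nkx6.1 had no value in the many-empty set, so that the block left a single bGAL array or changed nothing. Over all alternatives the named genes, apart from Vgf and Nkx6-1 in the comparisons given below, gave 2720 results on the same side, 587 that no longer passed, 101 that newly passed and 20 that changed sign; the lists called gave 283 on the same side, 25 that no longer passed and 0 whose test changed direction. Mitosis and G1/S passed in both comparisons with bGAL under every alternative run. Array weights raised the counts of probes most, and the weights themselves ran from 0.0557 (Nkx6.1 2) to 4.16 (Pdx1 3). Signal over background was not analysed here, since the values are log ratios alone, and an alternative without dim probes was not run for that reason. Another log scale was not run because the values are logs already. Settings that leave arrays out have fewer arrays by construction; for the other changes here the cause was not tested.

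Probes passing for Nkx6.1 against bGAL, Pdx1 against bGAL and Nkx6.1 against Pdx1 (115, 98 and 39) numbered 1670, 2633 and 759 with array weights, where 36.5%, 36.0% and 49.1% of calls were higher instead of 64.4%, 80.6% and 10.3%. A variance trend with robust moderation gave 66 and 57 in the first pair. The array set as a block gave 13 and 21. Within the few-empty arrays, with their lone bGAL array, both limma counts were lower still. Unadjusted p under 0.05 were fewer there than chance gives, in both comparisons. Only the arrays compared gave 27 in the first comparison. For Nkx6.1 against Pdx1, quantile normalization gave 86, one spread 86 and the block without Nkx6.1 2 gave 89. One spread also moved the share of higher calls to 70.3% for Pdx1 against bGAL and to 24.4% between the factors. Quantile normalization moved the median of all probes from -0.08 and -0.10 to 0.00 and -0.02. Leaving out each array gave 39 to 595, 16 to 432 and 14 to 81.

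The shared calls (33) numbered 18 with a variance trend, 1068 with array weights, 6 with the array set as a block, 0 within the few-empty arrays and a median of 0 with separate controls (8 at most); leaving out each array gave 7 to 289.

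Lists passing (5, 4 and 2) numbered 8 and 11 in the comparisons with bGAL under quantile normalization, 8 for Nkx6.1 against bGAL with array weights, 9 there with the block without Nkx6.1 2, 7 for Pdx1 against bGAL with the array set as a block and 11 with one spread, and 1 between the factors over complete probes and 9 with one spread. An estimated correlation gave 2 for Nkx6.1 against bGAL and 0 between the factors, and fry 9 and 1. Leaving out each array gave 4 to 8, 3 to 6 and 1 to 4.

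The replicate numbers did not pair the arrays: over 11 pairs with the same number the correlation of the arrays' deviations ran from -0.24 to 0.47, and the consensus correlation of the block was 0.00755. The replicate number as a fixed block gave 21, 22 and 19 probes, 3 shared calls and 7 lists for Pdx1 against bGAL, while a random block gave 118, 99 and 40.

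For Vgf, Nkx6.1 against bGAL, the difference passed with 2.83 under quantile normalization (adjusted p = 0.0122), 2.02 over complete probes (0.0424), 1.54 with array weights (0.00239), 1.67 with the block without Nkx6.1 2 (0.0226) and 1.91 with one spread (0.00438); leaving out each array gave 1.53 to 2.22. For Pdx1 against bGAL it was 0.25 under quantile normalization, and -0.48 to -0.23 without each array. The Nkx6-1 probe in Nkx6.1 against bGAL gave 0.50 under quantile normalization and -0.69 to -0.32 without each array.

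Signs also changed in differences that had not passed. Under quantile normalization these were Abcc8 (0.57), Nkx6-1 (0.75) and Nucb2 (0.67) for Pdx1 against bGAL, Nucb2 for Nkx6.1 against bGAL (0.49), and Nkx6-1 (-0.24) and Slc2a2 (-0.47) between the factors. Within the few-empty arrays they were Dusp6 (-0.045) and Rfx6 (0.11) for Pdx1 against bGAL and Nkx6-1 between the factors (-0.041). With the array set as a block they were Gadd45b for Pdx1 against bGAL (-0.10) and Nkx6-1 between the factors (-0.016), and without Nkx6.1 2 as well Gadd45b (-0.20) and, for Nkx6.1 against bGAL, Ptprn2 (0.10). With one spread they were Nkx6-1 (0.077) and Nucb2 (0.19) for Pdx1 against bGAL and Gipr (-0.34), Nkx6-1 (-0.41) and Slc2a2 (-0.91) between the factors. The Nkx6-1 difference between the factors was -0.04 without Nkx6.1 1 and -0.18 without Pdx1 2, and ran from -0.18 to 0.32 over all arrays left out in turn.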

Other observations

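In this part the scaling to one spread and the array set as a block were chosen only after the data were seen; the list tests and the splits of the arrays were chosen earlier. Genes outside the groups already described were chosen after their values were seen: Bik, a pro-apoptotic gene, was the 1 of 15 apoptosis regulators that passed, higher under Nkx6.1 by 1.51 (SE 0.274, limma adjusted p = 0.0286), and by 1.54 under Pdx1 without passing (adjusted p = 0.0523). Id1, a repressor of differentiation, was the 1 of 19 islet transcription factors that passed, higher under Nkx6.1 by 1.25 (adjusted p = 0.0410). Lmo4 was the 1 of 13 islet disallowed genes, which beta cells normally keep low, that passed, higher under Pdx1 by 2.52 (adjusted p = 0.0196). The second probe of Unc13c passed for Pdx1 against bGAL (2.27, adjusted p = 0.0168) and between the factors (-2.06, adjusted p = 0.0151), where the probe named by the rule did not.

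Lists of metabolism and secretion did not pass camera in any comparison with all arrays as deposited and no block. For Nkx6.1 and then Pdx1 against bGAL, the medians were -0.32 and -0.17 for cholesterol and fatty acid synthesis (19 genes, adjusted p = 0.0833 and 0.477; fry passed under Nkx6.1 with adjusted p = 0.0379 over 16 genes), -0.44 and -0.52 for ion channels (16 genes, adjusted p = 0.163 and 0.0683), -0.24 and -0.28 for the hypoxia response (16 genes), -0.04 and -0.17 for glycolysis (16 genes), -0.08 and 0.07 for mitochondrial energy metabolism (30 genes), -0.12 and -0.18 for the unfolded protein response (24 genes), 0.04 and -0.53 for exocytosis (19 genes), 0.01 and -0.04 for cAMP signalling (22 genes), 0.11 and -0.04 for ribosomal proteins (33 genes), -0.06 and -0.14 for islet transcription factors, -0.10 and -0.01 for apoptosis regulators and 0.01 and 0.09 for islet disallowed genes. Under quantile normalization the hypoxia, cholesterol and glycolysis lists passed downward under Pdx1 (-0.64, -0.21 and -0.40) and hypoxia and cholesterol under Nkx6.1 (-0.40 and -0.27). In the fit with the array set as a block the unfolded protein response, glycolysis and hypoxia lists passed downward under Pdx1 (-0.35, -0.29 and -0.28, adjusted p = 0.0421, 0.0339 and 0.0421). Without Nkx6.1 2 the ion channels passed downward under Nkx6.1 (-0.42, adjusted p = 0.0330). Quantile normalization turned the sign of both medians for the unfolded protein response (0.06 and 0.24), islet transcription factors (0.48 and 0.04) and islet disallowed genes (-0.14 and -0.21). The same normalization also turned mitochondrial energy metabolism (0.05) under Nkx6.1, and exocytosis (0.29), cAMP signalling (0.23), ribosomal proteins (0.02) and apoptosis regulators (0.16) under Pdx1. Neuropeptides under Nkx6.1 had a median of 0.07 and a mean of -0.34, with Calcb and Gast lower and the test downward (adjusted p = 0.900); with arrays scaled to one spread the median was -0.06.

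Median, mean and test differed in sign for other lists that did not pass. For Nkx6.1 against bGAL the median and mean were 0.40 and -0.05 for acinar cells, -0.10 and 0.02 for apoptosis regulators and -0.04 and 0.05 for glycolysis. For Pdx1 against bGAL the list of alpha and other hormone cells had a median of -0.22 with an upward test, and passed upward under quantile normalization (0.87, adjusted p = 0.0152); it was lower under Nkx6.1 than under Pdx1 by a median of -0.15 (camera adjusted p = 0.456), and passed without Nkx6.1 replicate 2 (-0.25, adjusted p = 5.05e-04).

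Other splits of the arrays were run for each count. For Nkx6.1 against bGAL chance could not be excluded: the real split gave 115 probes and the highest other split 863, with 5 of 100 splits giving as many. That split put bGAL 1, 2, 3 and 5 with Nkx6.1 1 and so followed the array set with many empty values; a count several times the real one points to a structure of the samples, and with the set as a block 13 probes passed. For Pdx1 against bGAL chance could not be excluded either, with 98 probes against 504 for the split of bGAL 1, 2 and 3 from the rest, all of them arrays of the same set, and 3 of 56 splits giving as many; the blocked count was 21. For Nkx6.1 against Pdx1 the real split gave 39 probes against 1 for the highest other split. Only 1 of 56 splits, the real one, gave as many, the smallest share that these arrays allow. Chance alone was thus unlikely there, but so few splits cannot exclude it.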
